A study of Homo sapiens with 97 samples.

How the data were processed

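RNA was measured in HEK293T cells expressing APEX2 constructs, in 97 libraries of 49 groups. The deposited counts per gene are raw integers; per the submitters' processing notes, which name Trimmomatic, STAR, HTSeq, SAMtools and bedtools without versions or settings, reads were aligned to GRCh38 (hg38). The deposited log2 fold changes and p-values per gene come from the authors' use of DESeq2, per those notes. The headers do not say whether these p-values are adjusted. Those columns were summarised once and entered no test. Each table holds 60675 gene identifiers, of which 57055 took their name from GENCODE 29, 390 only from the deposited tables and 3230 had none.

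Groups followed the labels: construct, peroxide (labelled) or none (unlabelled), drug or time of nocodazole, poly(A) or total RNA, and fraction. Tests were made within a table, with 1 exception, in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The untreated NES and OMM libraries, deposited in another table, were joined to the drug libraries by gene identifier. Drug against untreated thus also compares sets of libraries, and a drug effect was not told from a difference between sets. Tests used TMM scaling, the default filter on low counts, trended dispersion and the quasi-likelihood F test in 1 model of group means per table. The p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison. An adjusted p under 0.05 was called. Labelled was set against unlabelled for each construct, differences of such contrasts against each other for ERM, OMM and NLS against NES, for poly(A) against total RNA, for each drug against untreated cells, for cycloheximide against puromycin and for OMM against NES over time, and the nuclear against the cytosol fraction. Each nocodazole time was set against the mean of the unlabelled libraries of 3 and 30 min, since the other times had none. The standard error is the absolute log2 fold change over the square root of F. Genes without a count in 1 of the groups have no finite fold change and are given as lower bounds against a floor of 3 counts. In libraries that lacked many well-expressed genes a missing count may not mean absent RNA. There the bound holds for the counts and not for the RNA.

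The comparisons, 24 gene lists written from general knowledge, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over all lists and comparisons of a table, and again with an estimated correlation; calls were also counted adjusted over the list alone. Where members without a count in a group change the median, the median with bounds follows in brackets. Named genes are up to 6 of the largest higher and 4 of the largest lower genes with a mean of at least 5 CPM, an adjusted p under 0.05, a symbol that is not a clone name and the same direction in every replicate; up to 4 members of a described list with the smallest p; and 13 landmarks. Not every gene these rules allow is described: to keep the text short a subset was taken after the results were seen, mostly leaving out genes whose calls hung on single libraries, so the genes described are steadier than the full set. A few items withheld for evaluation are not reported here.

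Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, only the libraries of the comparison, a replicate block, other controls, a log2 fold change of at least 1 as well, the technical repeat added, and each library left out in turn, where a group left with 1 library was taken to vary like the others. Chosen after seeing the data were the removal of low-complexity libraries (more than 2 percent of genes with a mean of at least 5 CPM lacking a count, where each group kept a library), counts among genes with a mean of at least 5 CPM, and NES unlabelled libraries as controls for OMM with nocodazole. Explanations were tested with 10000 random lists drawn from the 50 nearest genes, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were made with matplotlib 3.10.9.

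The method was tested on simulated data with the means and dispersions of each table. Whether the real libraries, some of low complexity, follow this model was not tested. The rates below thus do not tell how many real calls of edgeR or DESeq2 are false. Of changes of 2, 4 and 8-fold in NLS edgeR called 23.9, 50.7 and 77.3 percent, and of unchanged genes 1 was called by edgeR and 96 by DESeq2; in OMM with cycloheximide the values were 1.5, 28.4 and 54.5 percent, 1 and 103, and in fractionation 70.1, 95.5 and 100 percent, 6 and 34. The technical repeat of MITO labelled 2 was left out of the tests because its label gives it as no further replicate. Reads were not used here, so counts of overlapping antisense genes, pseudogenes and paralogs stand as deposited.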

Results

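The deposited tables hold RNA counts from human HEK293T cells carrying APEX2 peroxidase constructs directed to 9 places: the nucleus (NLS), nucleolus (NIK), nuclear lamina (LMA), nuclear pore (NucPore), cytosol (NES), cytosolic face of the endoplasmic reticulum (ERM), ER lumen (KDEL), outer mitochondrial membrane (OMM) and mitochondrial matrix (MITO). RNA tagged with biotin-phenol and hydrogen peroxide (labelled) was set against the same procedure without peroxide (unlabelled), with n = 2 libraries per group. Further tables cover total RNA of the MITO construct, nuclear and cytosolic fractions, OMM and NES cells with cycloheximide, puromycin or CCCP, and OMM and NES cells along a nocodazole time course, 97 libraries in 49 groups in all. Depth was 9.33 to 76.71 M counts in the table of 9 constructs, 22.75 to 55.76 with the drugs, 15.47 to 33.97 with nocodazole, 2.84 to 76.71 in the MITO table and 34.96 to 44.97 for the fractions. Coordinates refer to GRCh38: ALDH18A1 (ENSG00000059573), for example, lies on chromosome 10 at 95605929 to 95656706. A value after a gene is its log2 fold change ± standard error, which covers counting error and the spread of replicates that may be technical. Every gene given as higher or lower had an adjusted p under 0.05 and moved that way in both replicates. Counts within the list are adjusted over the genes of that list alone. Well-expressed genes are those with a mean of at least 5 CPM in the table.

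The first question, set by the MITO labels, was which RNAs lie in the matrix. Transcripts of the mitochondrial genome rose most: MT-ND5 (5.39 ± 0.36) and MT-ND6 (5.37 ± 0.39) of respiratory complex I, MT-CO1 (4.43 ± 0.27) of complex IV and the large ribosomal RNA MT-RNR2 (3.79 ± 0.27). Of mitochondrial messenger RNAs 13 of 13 were higher and 0 lower (13 and 0 within the list, median 3.98, adjusted p = 1.01e-59). Several nuclear transcripts rose as well: the alpha tubulins TUBA1B (3.08 ± 0.15), TUBA1A (2.72 ± 0.29) and TUBA1C (2.36 ± 0.18), the spindle motor KIF11 (2.44 ± 0.22), MCCC2 (2.73 ± 0.21), a leucine-degrading matrix enzyme, and the complex IV subunit COX8A (2.17 ± 0.25). The tubulin list had 3 of 12 higher and 0 lower (3 and 1 within the list, median -0.03, mean 0.47 and test upward, adjusted p = 0.0015, adjusted p = 0.112 with an estimated correlation). Matrix enzymes had 4 of 88 higher and 0 lower (5 and 1 within the list, median -0.04, mean 0.04 and test downward, adjusted p = 0.178). BTF3 (-1.05 ± 0.17), of the nascent polypeptide-associated complex, fell, and of cytosolic ribosome transcripts 0 of 76 were higher and 6 lower (1 and 11 within the list, median -0.30, adjusted p = 7.71e-15, adjusted p = 0.0885 with an estimated correlation). In all 198 genes were higher and 41 lower of 22680 tested. Reads of MTCO1P12 (4.23 ± 0.57), a nuclear copy of MT-CO1, and of the near-identical TUBA1A, TUBA1B and TUBA1C could be interchanged in counting. MITO calls numbered 110 without labelled 2 and 108 without unlabelled 1. BTF3 was not called with only the libraries of the comparison (adjusted p = 0.183). For matrix enzymes the adjusted p was 0.00791 with the controls of all 9 constructs.

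**Figure D1:**
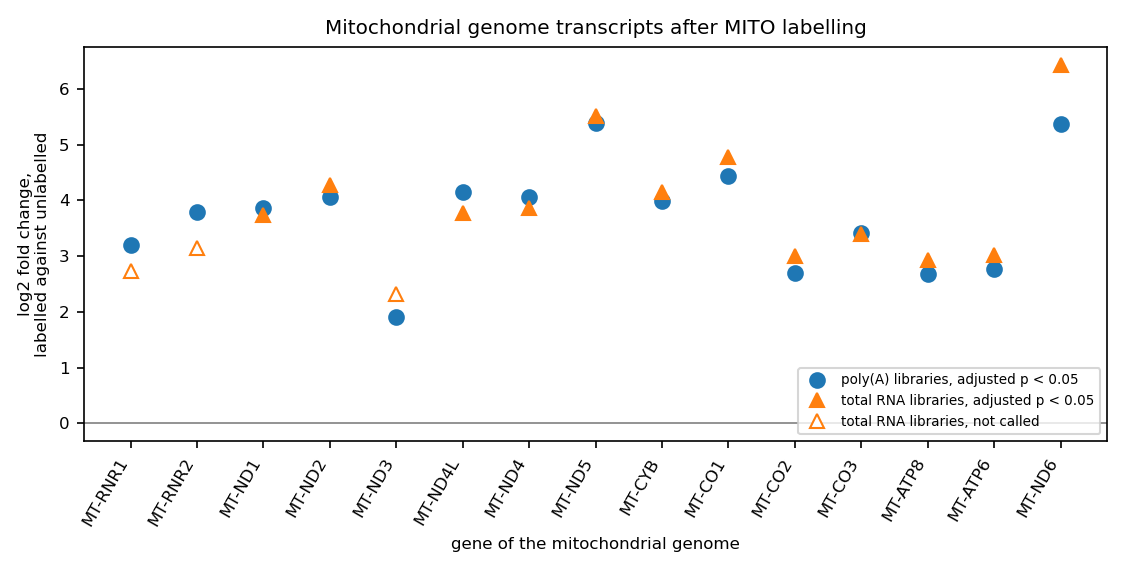
Log2 fold change (labelled against unlabelled, y axis) of mitochondrial genome transcripts (x axis) in the MITO construct, circles for poly(A) and triangles for total RNA libraries. Filled symbols have an adjusted p under 0.05, open symbols were not called.

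Total RNA of the MITO construct asked the same question without poly(A) selection. MT-ND6 (6.43 ± 0.72) and MT-ND5 (5.51 ± 0.70) rose again, and TUBA1A (2.30 ± 0.26) rose with them. MT-TW, the mitochondrial tryptophan transfer RNA, had no counts in unlabelled libraries and rose at least 933-fold against a floor of 3 counts. Of mitochondrial messenger RNAs 12 of 13 were higher and 0 lower (13 and 0 within the list, median 3.78, adjusted p = 5.24e-25, adjusted p = 0.679 with an estimated correlation). Mitochondrial genes held 83 and 65 percent of counts in the labelled and 27.7 and 26.6 percent in the unlabelled libraries, and labelled 1 lacked 5.14 percent of well-expressed genes. The test found 92 genes higher and 2 lower of 14911. MITO total RNA calls numbered 4 without labelled 1, 641 without labelled 2, 41 without unlabelled 2 and 0 without unlabelled 1 (edgeR, 1853 at an unadjusted p under 0.05). MITO total RNA counts were 50 with only the libraries of the comparison and 26 without low-complexity libraries. MT-ND6, MT-ND5 and MT-TW lost their calls without unlabelled 2, and MT-ND5 and TUBA1A lost theirs without labelled 1. Set against total RNA labelling, poly(A) labelling changed 0 genes by edgeR, with 600 at an unadjusted p under 0.05 and 6 by DESeq2. MT-ND6 (-1.02 ± 0.80) and TUBA1B (0.44 ± 0.49) were not called, and the technical repeat of labelled 2 left the count at 0. Poly(A) against total RNA calls numbered 1 without poly(A) unlabelled 2.

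ERM labelling asked which RNAs lie at the cytosolic face of the ER. SCD (2.76 ± 0.14), the fatty acid desaturase, and SQLE (2.15 ± 0.22) of cholesterol synthesis rose, and of sterol and lipid enzymes 31 of 59 were higher and 0 lower (36 and 1 within the list, median 1.01, adjusted p = 2.12e-20). Membrane and secreted proteins rose too, among them the amino acid transporter SLC7A5 (2.09 ± 0.23), the transferrin receptor TFRC (1.77 ± 0.19), the chaperone CANX (2.10 ± 0.17), the calcium binder CALU (2.09 ± 0.19) and the translocon subunit SEC61A1 (1.7 ± 0.18). Plasma membrane transcripts had 61 of 115 higher and 1 lower (73 and 1 within the list, median 1.36, adjusted p = 5.13e-33) and ER folding 24 of 63 higher and 10 lower (27 and 10 within the list, median 0.37, adjusted p = 2.83e-07). UFL1 (2.90 ± 0.32), the ligase that attaches UFM1 at the ER, and TOMM20 (1.40 ± 0.15), an import receptor of mitochondria, rose, and HSPA5 (0.27 ± 0.19) was not called. Products of free ribosomes fell: RPS29 (-3.39 ± 0.22) of the small ribosomal subunit, ATP5MC1 (-3.60 ± 0.25) and COX6B1 (-3.50 ± 0.27) of the respiratory chain and ACTB (-1.10 ± 0.15). Ribosomal transcripts had 0 of 76 higher and 72 lower (0 and 75 within the list, median -2, adjusted p = 8.61e-82) and the nuclear-encoded respiratory chain 0 of 76 higher and 67 lower (0 and 71 within the list, median -1.98, adjusted p = 1.49e-50). The test called 1193 genes higher and 1724 lower of 22680. ERM labelled 1 lacked 4.9 percent of well-expressed genes. ERM calls numbered 1905 without unlabelled 2. ERM counts were 1857 with only the libraries of the comparison. HSPA5 was called with the controls of all 9 constructs (adjusted p = 0.000264).

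Tested directly against NES labelling, the ERM held more of the cholesterol gene SQLE (2.87 ± 0.31), of SCD (2.42 ± 0.19), UFL1 (4.14 ± 0.44), TFRC (2.66 ± 0.26) and CANX (2.54 ± 0.23), and of the chaperone HSPA5 (1.33 ± 0.26). TOMM20 (1.44 ± 0.22) was also higher, while RPS29 (-2.13 ± 0.29) and ATP5MC1 (-2.36 ± 0.33) were lower. ER folding had 33 of 63 higher and 0 lower (38 and 4 within the list, median 1.27, adjusted p = 1.21e-35). Sterol and lipid enzymes had 24 of 59 higher and 0 lower (32 and 0 within the list, median 1.27, adjusted p = 7.19e-36) and ribosomal transcripts 0 of 76 higher and 41 lower (0 and 65 within the list, median -1.10, adjusted p = 8.63e-31). Higher genes numbered 487 and lower genes 383 of 22680. ERM against NES calls rose without ERM labelled 2 or NES unlabelled 2 and fell without any other library. ERM against NES counts were 353 with only the libraries of the comparison.

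OMM labelling asked which RNAs lie at the outer mitochondrial membrane. Transcripts of matrix proteins led: GLDC (3.91 ± 0.39) and AASS (3.82 ± 0.36) of amino acid breakdown, the phosphatase regulator PDPR (3.58 ± 0.27), the mitochondrial tRNA synthetases LARS2 (3.45 ± 0.25) and IARS2 (3.00 ± 0.18), and ALDH18A1 (3.32 ± 0.19) of proline synthesis. The matrix enzyme list as a whole was split, with 15 of 88 higher and 10 lower (22 and 12 within the list, median 0.00, mean 0.34 and test upward, adjusted p = 0.264). Secretory transcripts rose beside them, including SCD (1.94 ± 0.14), CANX (1.66 ± 0.17), CALU (1.79 ± 0.19), the oligosaccharyltransferase subunit MAGT1 (1.81 ± 0.18) and the lysosomal PSAP (1.5 ± 0.17). Secreted proteins had 33 of 79 higher and 0 lower (45 and 0 within the list, median 1.47 (1.42 with bounds), adjusted p = 2.3e-24). Lysosome had 21 of 62 higher and 0 lower (33 and 0 within the list, median 0.93, adjusted p = 1.11e-15) and ER folding 28 of 63 higher and 1 lower (32 and 5 within the list, median 0.81, adjusted p = 1.61e-12). Lower were MT-CO1 (-1.42 ± 0.24) and RPL24 (-1.37 ± 0.17). Mitochondrial messenger RNAs had 0 of 13 higher and 12 lower (0 and 12 within the list, median -1.48, adjusted p = 3.4e-19) and ribosomal transcripts 0 of 76 higher and 40 lower (0 and 56 within the list, median -0.81, adjusted p = 2.1e-46). Of 22680 genes 681 were higher and 450 lower. OMM unlabelled 2 lacked 3.95 percent of well-expressed genes. OMM calls numbered 638 without labelled 1, 549 without labelled 2, 2180 without unlabelled 1 and 441 without unlabelled 2. OMM counts were 463 with only the libraries of the comparison. For matrix enzymes the adjusted p was 0.000158 by DESeq2. Matrix enzymes had a list adjusted p = 0.0428 without labelled 2.

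Against NES labelling the OMM held more GLDC (4.25 ± 0.52), PDPR (3.88 ± 0.36), IARS2 (3.63 ± 0.24) and ALDH18A1 (3.62 ± 0.26), and more CALU (2.16 ± 0.27), CANX (2.10 ± 0.23), PSAP (1.89 ± 0.24) and HSPA5 (1.53 ± 0.26). Matrix enzymes had 17 of 88 higher and 0 lower (18 and 2 within the list, median 0.27, adjusted p = 4.04e-07). ER folding had 32 of 63 higher and 0 lower (43 and 0 within the list, median 1.40, adjusted p = 2.01e-50) and secreted proteins 28 of 79 higher and 0 lower (48 and 0 within the list, median 1.65, adjusted p = 6.88e-36). Calls came to 359 higher and 32 lower of 22680. OMM against NES calls numbered 168 without NES labelled 2, 258 without OMM labelled 1, 1020 without NES unlabelled 2, 1113 without OMM unlabelled 1 and 223 without OMM unlabelled 2. OMM against NES counts were 130 with only the libraries of the comparison.

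NES labelling asked which RNAs lie in the cytosol. Ribosomal and respiratory transcripts fell: RPS4X (-1.27 ± 0.16), RPL5 (-1.29 ± 0.15), COX7B (-1.51 ± 0.24) and ATP5PB (-1.40 ± 0.21). MT-CO1 (-1.67 ± 0.24) and MT-ND3 (-2.10 ± 0.28) fell too, as did the ER chaperone HSP90B1 (-1.06 ± 0.15), the splicing factors SRSF3 (-1.07 ± 0.16) and SRSF7 (-1.29 ± 0.18), and the snoRNA hosts GAS5 (-1.7 ± 0.27) and SNHG5 (-1.65 ± 0.26). Ribosomal transcripts had 0 of 76 higher and 53 lower (0 and 66 within the list, median -1.02, adjusted p = 1.27e-73). Mitochondrial messenger RNAs had 0 of 13 higher and 13 lower (0 and 13 within the list, median -1.74, adjusted p = 7.75e-29), the respiratory chain 0 of 76 higher and 29 lower (0 and 50 within the list, median -0.84, adjusted p = 2.89e-37) and splicing factors and kinases 0 of 44 higher and 12 lower (1 and 24 within the list, median -0.56, adjusted p = 5.43e-15). Among the rises was MBD3 (1.76 ± 0.35), a chromatin repressor, and the nuclear MALAT1 (-1.28 ± 0.48) was not called. Higher genes were 313 and lower genes 567 of 22680. NES unlabelled 1 lacked 3.31 percent of well-expressed genes. NES calls rose without unlabelled 2 and fell without any other library. NES counts were 0 with only the libraries of the comparison (edgeR, 2806 at an unadjusted p under 0.05). MBD3 lost its call without unlabelled 1 (adjusted p = 0.167). MALAT1 was called without low-complexity libraries (adjusted p = 9.18e-05).

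KDEL labelling asked which RNAs lie in the ER lumen, and edgeR called 0 of 22680 genes, with 46 at an unadjusted p under 0.05 and 0 by DESeq2. HSPA5 (-0.02 ± 0.19) and SSR2 (-0.30 ± 0.17), both made at the ER, and MT-CO1 (0.55 ± 0.24) were not called. ER folding had 0 of 63 called (0 and 0 within the list, median -0.15, adjusted p = 3.35e-10) and mitochondrial messenger RNAs 0 of 13 called (0 and 0 within the list, median 0.51, adjusted p = 4.75e-10, adjusted p = 0.1 with an estimated correlation). With the controls of all 9 constructs the median of mitochondrial messenger RNAs was 0.12 and their test turned downward (adjusted p = 0.673). MT-CO1 was called with no filter on low counts (adjusted p = 5.84e-11). Mitochondrial messenger RNAs had a list adjusted p = 0.772 without unlabelled 1.

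**Figure D2:**
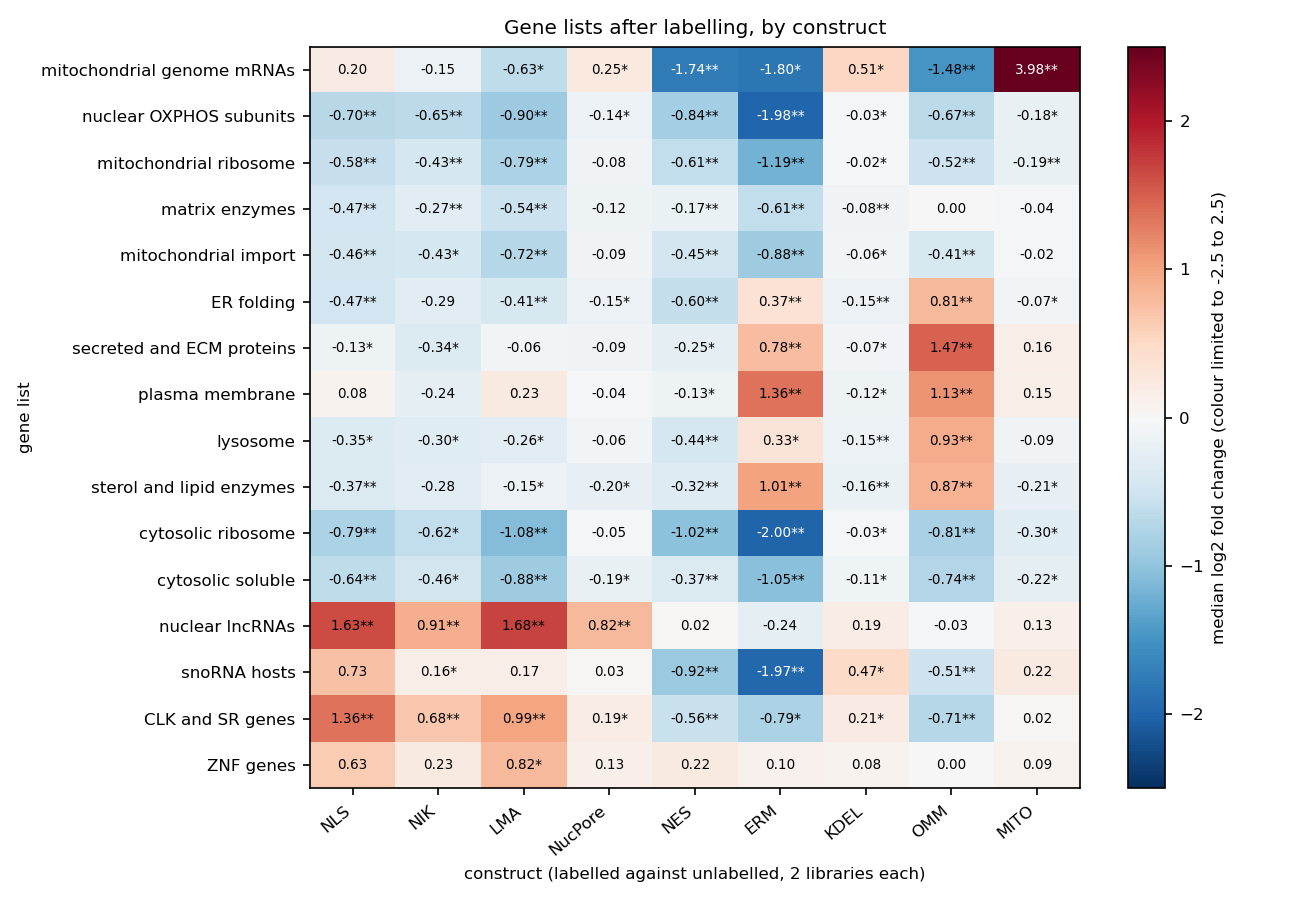
Median log2 fold change (labelled against unlabelled, colour) of each gene list in each of the 9 constructs. A star marks a list with an adjusted p under 0.05 at the preset correlation and 2 stars one that also passed with an estimated correlation.

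NLS labelling asked which RNAs lie in the nucleus. The nuclear long noncoding RNAs MALAT1 (3.65 ± 0.52), NEAT1 (2.74 ± 0.43) and TUG1 (1.5 ± 0.22) rose, as did the snoRNA hosts SNHG17 (2.26 ± 0.40) and GAS5 (1.49 ± 0.27). Transcripts of RNA processing factors, many of which retain introns in the nucleus, rose with them: DDX17 (2.32 ± 0.19), DDX39B (2.47 ± 0.21), NKTR (2.55 ± 0.29) and the glycosyltransferase OGT (2.05 ± 0.21). Splicing factors and kinases had 31 of 44 higher and 0 lower (35 and 1 within the list, median 1.36, adjusted p = 2.54e-22) and nuclear long noncoding RNAs 4 of 26 higher and 0 lower (5 and 0 within the list, median 1.63, adjusted p = 0.000143). Transcripts translated in the cytosol fell: RPS18 (-1.41 ± 0.16), ACTB (-1.35 ± 0.15), the glycolytic GAPDH (-1.08 ± 0.18) and PGK1 (-1.07 ± 0.15) and the proteasome subunit PSMB3 (-1.84 ± 0.26). Ribosomal transcripts had 0 of 76 higher and 45 lower (1 and 57 within the list, median -0.79, adjusted p = 9.22e-45) and soluble cytosolic proteins 0 of 60 higher and 23 lower (1 and 40 within the list, median -0.64, adjusted p = 1.95e-29). MT-ND6 (2.04 ± 0.34) rose and MT-CO1 (0.12 ± 0.24) was not called, and with the controls of all 9 constructs MT-CO1 was -0.89. Of 22680 genes tested 631 were higher and 548 lower. NLS calls fell without any 1 library. NLS counts were 4788 with only the libraries of the comparison. MT-ND6 was not called with the controls of all 9 constructs (adjusted p = 0.402).

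Against NES labelling the NLS construct held more MALAT1 (4.93 ± 0.70), NEAT1 (4.12 ± 0.60), DDX39B (3.69 ± 0.29), HNRNPH1 (2.53 ± 0.23) and the snoRNA hosts GAS5 (3.19 ± 0.38) and SNHG1 (2.61 ± 0.36), and more MT-ND6 (3.98 ± 0.47). ACTB (-1.39 ± 0.21), the glycolytic GPI (-1.43 ± 0.27) and the stress gene SESN2 (-1.88 ± 0.36) were lower. Splicing factors and kinases had 28 of 44 higher and 0 lower (37 and 1 within the list, median 1.55, adjusted p = 6.59e-47). SnoRNA hosts had 7 of 25 higher and 0 lower (11 and 0 within the list, median 1.92 (1.59 with bounds), adjusted p = 3.42e-10) and mitochondrial messenger RNAs 12 of 13 higher and 0 lower (13 and 0 within the list, median 1.90, adjusted p = 2.12e-20). The mitochondrial genome held 4.73 and 4.92 percent of counts in NES unlabelled libraries, against 2.1 and 1.65 percent in NLS unlabelled ones. Labelled libraries differed less (2.09 and 2.21 percent in NLS, 2.02 and 1.12 in NES). Genes higher numbered 307 and genes lower 209 of 22680. NLS against NES calls rose without NES unlabelled 2 and fell without any other library.

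LMA labelling asked which RNAs lie at the nuclear lamina. DDX17 (2.78 ± 0.19), NKTR (2.73 ± 0.29) and the splicing factor SRSF11 (2.16 ± 0.24) rose with the noncoding NEAT1 (2.43 ± 0.43), TUG1 (1.96 ± 0.23) and OIP5-AS1 (1.56 ± 0.23), and zinc finger transcripts joined them, with ZNF121 (4.33 ± 0.37), ZNF621 (2.65 ± 0.32) and ZNF24 (1.56 ± 0.20). Zinc fingers had 37 of 421 higher and 0 lower (41 and 0 within the list, median 0.82, adjusted p = 0.000691, adjusted p = 0.235 with an estimated correlation) and splicing factors and kinases 25 of 44 higher and 0 lower (29 and 0 within the list, median 0.99, adjusted p = 2.36e-17). ALDOA (-1.56 ± 0.20) and GAPDH (-1.45 ± 0.18) of glycolysis and the cytokine MIF (-2.26 ± 0.45) fell, and of ribosomal transcripts 0 of 76 were higher and 61 lower (0 and 65 within the list, median -1.08, adjusted p = 1.91e-58). CCT6P1, a pseudogene whose reads could come from its parent CCT6A, rose at least 387-fold against a floor of 3 counts. MT-ND6 (1.05 ± 0.33) rose and was -0.37 with the controls of all 9 constructs. In this construct 833 genes were higher and 908 lower of 22680. LMA calls numbered 802 without labelled 1, 1005 without labelled 2 and 1090 without unlabelled 1. LMA counts were 4417 with only the libraries of the comparison. MT-ND6 lost its call without labelled 1 (adjusted p = 0.233), without labelled 2 (adjusted p = 0.0731), without unlabelled 1 (adjusted p = 0.193) and without unlabelled 2 (adjusted p = 0.198).

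NIK labelling asked which RNAs lie in the nucleolus. MALAT1 (2.41 ± 0.50) rose, together with DDX17 (1.66 ± 0.18), DDX39B (1.67 ± 0.20), the splicing factor SRSF6 (1.39 ± 0.17) and the antisense HNRNPU-AS1 (2.83 ± 0.41), whose reads could belong to the gene it overlaps. Splicing factors and kinases had 21 of 44 higher and 0 lower (28 and 0 within the list, median 0.68, adjusted p = 2.75e-27) and nuclear long noncoding RNAs 3 of 26 higher and 1 lower (3 and 1 within the list, median 0.91, mean -0.05 and test upward, adjusted p = 0.00165). COX6B1 (-2.01 ± 0.25), RPL36 (-1.61 ± 0.22), RPS19 (-1.31 ± 0.18) and ACTB (-1.03 ± 0.15) fell, and the membrane protein transcript SEL1L3, without counts in labelled libraries, fell at least 294-fold against a floor of 3 counts. Ribosomal transcripts had 0 of 76 higher and 41 lower (2 and 52 within the list, median -0.62, adjusted p = 9.55e-18, adjusted p = 0.0621 with an estimated correlation). The test gave 290 higher and 899 lower of 22680 genes. NIK labelled 1 and 2 lacked 5.96 and 2.88 percent of well-expressed genes. Of NIK calls 188 had a group without a count and 73 a group of 1 to 3 counts. NIK calls numbered 2441 without labelled 2, 587 without unlabelled 1 and 541 without unlabelled 2. NIK counts were 0 with only the libraries of the comparison (edgeR, 2952 at an unadjusted p under 0.05).

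NucPore labelling asked which RNAs lie at the nuclear pore, and edgeR called 0 of 22680 genes, with 1341 at an unadjusted p under 0.05 and 177 by DESeq2. NEAT1 (1.55 ± 0.42), MALAT1 (0.96 ± 0.47) and NKTR (1.00 ± 0.27) were not called. As lists, splicing factors and kinases had 0 of 44 called (7 and 0 within the list, median 0.19, adjusted p = 2.86e-08, adjusted p = 0.0782 with an estimated correlation) and nuclear long noncoding RNAs 0 of 26 called (1 and 0 within the list, median 0.82, adjusted p = 0.00578). NucPore labelled 1 and unlabelled 1 lacked 2.16 and 2.02 percent of well-expressed genes, and without low-complexity libraries 11 genes were higher and 28 lower. NucPore calls numbered 1 without labelled 1, 174 without labelled 2 and 95 without unlabelled 2. NEAT1 and NKTR were called by DESeq2 (adjusted p = 0.0418 and 0.0444), NEAT1 with no filter on low counts (adjusted p = 0.00131), NEAT1, MALAT1 and NKTR with the controls of all 9 constructs (adjusted p = 0.00446, 0.00199 and 0.00477) and NEAT1 and MALAT1 without low-complexity libraries (adjusted p = 1.14e-05 and 0.048). For nuclear long noncoding RNAs the adjusted p was 0.254 with the controls of all 9 constructs and 0.0768 among genes with a mean of at least 5 CPM. Splicing factors and kinases had a list adjusted p = 0.0752 without unlabelled 2, and nuclear long noncoding RNAs had a list adjusted p = 0.0954 without labelled 2.

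Fractionation of cells asked which RNAs are nuclear without APEX2. MALAT1 (4.52 ± 0.20), NEAT1 (4.20 ± 0.19), KCNQ1OT1 (4.78 ± 0.33) and MIR222HG (5.49 ± 0.31), all retained noncoding RNAs, were higher in the nuclear fraction, with the splicing kinase partner CCNL2 (3.76 ± 0.19). Transcripts made at the ER were also higher there, among them HSPA5 (2.05 ± 0.17), SCD (0.80 ± 0.17), the laminin LAMB2 (3.86 ± 0.20) and the receptor IGF2R (2.61 ± 0.19). RPL32 (-2.27 ± 0.19), ACTB (-1.98 ± 0.18), MT-ND4 (-4.70 ± 0.21) and MT-ATP6 (-4.72 ± 0.20) were lower, whereas MT-ND6 (2.71 ± 0.23) was higher. Plasma membrane transcripts had 95 of 113 higher and 1 lower (97 and 3 within the list, median 1.58, adjusted p = 2.29e-14, adjusted p = 0.29 with an estimated correlation). ER folding had 41 of 63 higher and 4 lower (41 and 4 within the list, median 0.85, adjusted p = 1.74e-06, adjusted p = 0.3 with an estimated correlation), ribosomal transcripts 1 of 76 higher and 70 lower (1 and 72 within the list, median -1.55, adjusted p = 7.41e-24, adjusted p = 0.3 with an estimated correlation) and mitochondrial messenger RNAs 1 of 13 higher and 12 lower (1 and 12 within the list, median -4.06, adjusted p = 1.47e-10, adjusted p = 0.29 with an estimated correlation). The nuclear fraction was higher for 6535 genes and lower for 5323 of 19115. MALAT1, NEAT1 and ACTB moved the same way in NLS against NES labelling, which shares no library with the fractions. Mitochondrial messenger RNAs moved the opposite way (median 1.90 there), with unlabelled libraries that differed in mitochondrial share. Across 18918 genes tested in both, the log2 fold changes had a Pearson correlation of 0.43 (0.5 among well-expressed genes), and genes are not independent replicates. Of 444 genes called in both, 399 (89.9 percent) had the same sign, 241 nuclear and 158 cytosolic, while 34 were higher in NLS and lower in the nuclear fraction and 11 the reverse. Fractionation counts were 7125 among genes with a mean of at least 5 CPM.

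**Figure D3:**
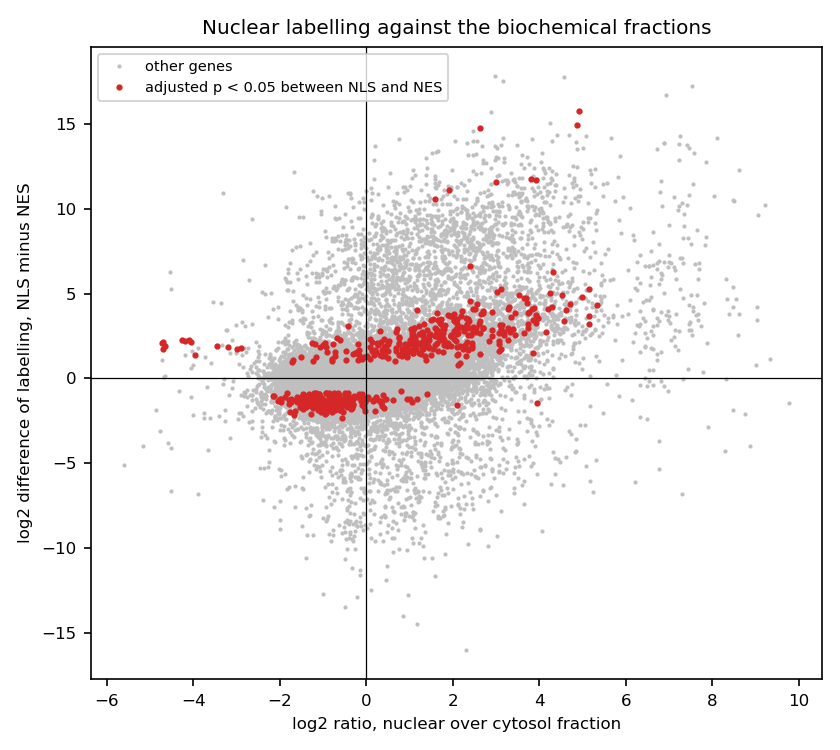
Log2 fold change of NLS against NES labelling (y axis) against that of nuclear against cytosol fraction (x axis), one point per gene tested in both. Red points had an adjusted p under 0.05 between NLS and NES labelling, grey points did not.

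Cycloheximide, which freezes ribosomes on messenger RNAs, was set against no drug to ask what holds RNAs at the OMM. In every comparison with untreated cells the untreated libraries came from another table, so a drug effect was not told from a difference between sets. Matrix and inner membrane protein transcripts rose: HADHA (3.56 ± 0.27) and HADHB (3.88 ± 0.33) of fatty acid oxidation, the chaperone HSPA9 (2.95 ± 0.23), the citrate synthase CS (2.93 ± 0.25), SDHA (3.04 ± 0.26), UQCRC1 (3.44 ± 0.26) and ATP5F1B (3.18 ± 0.20) of the ATP synthase. Matrix enzymes had 38 of 88 higher and 0 lower (51 and 0 within the list, median 1.5, adjusted p = 2.05e-37). Whereas the respiratory chain list had 9 of 76 higher and 0 lower (9 and 1 within the list, median 0.14, adjusted p = 0.126). The ER genes RPN1 (1.31 ± 0.26) and TRAM1 (2.12 ± 0.40) rose, and ER folding had 10 of 63 higher and 0 lower (21 and 0 within the list, median 0.56, adjusted p = 2.02e-07). SCD (0.22 ± 0.19) was not called. FAS, a death receptor without counts in 1 group, rose at least 546-fold against a floor of 3 counts and was -0.38 between the labelled libraries alone. With cycloheximide 382 genes were higher and 28 lower of 22078. The cycloheximide unlabelled libraries lacked 3.2 and 7.83 percent of well-expressed genes, and untreated unlabelled 2 lacked 3.8 percent. Of OMM cycloheximide calls 124 had a group without a count and 56 a group of 1 to 3 counts. OMM cycloheximide calls numbered 263 without cycloheximide labelled 1, 270 without cycloheximide labelled 2, 2727 without cycloheximide unlabelled 1, 628 without cycloheximide unlabelled 2, 186 without untreated labelled 1, 216 without untreated labelled 2 and 1147 without untreated unlabelled 1. OMM cycloheximide counts were 41 with only the libraries of the comparison and 246 between the labelled libraries alone. CS, TRAM1 and RPN1 were not called with only the libraries of the comparison (adjusted p = 0.0501, 0.314 and 0.0501) and TRAM1 and RPN1 between the labelled libraries alone (adjusted p = 0.162 and 0.137). SCD was called between the labelled libraries alone (adjusted p = 0.00198). For nuclear-encoded respiratory chain the adjusted p was 0.00787 by DESeq2 and 0.00824 with no filter on low counts. Nuclear-encoded respiratory chain had a list adjusted p = 0.00463 without cycloheximide unlabelled 2, 0.00918 without untreated labelled 1 and 0.000375 without untreated unlabelled 1.

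**Figure D4:**
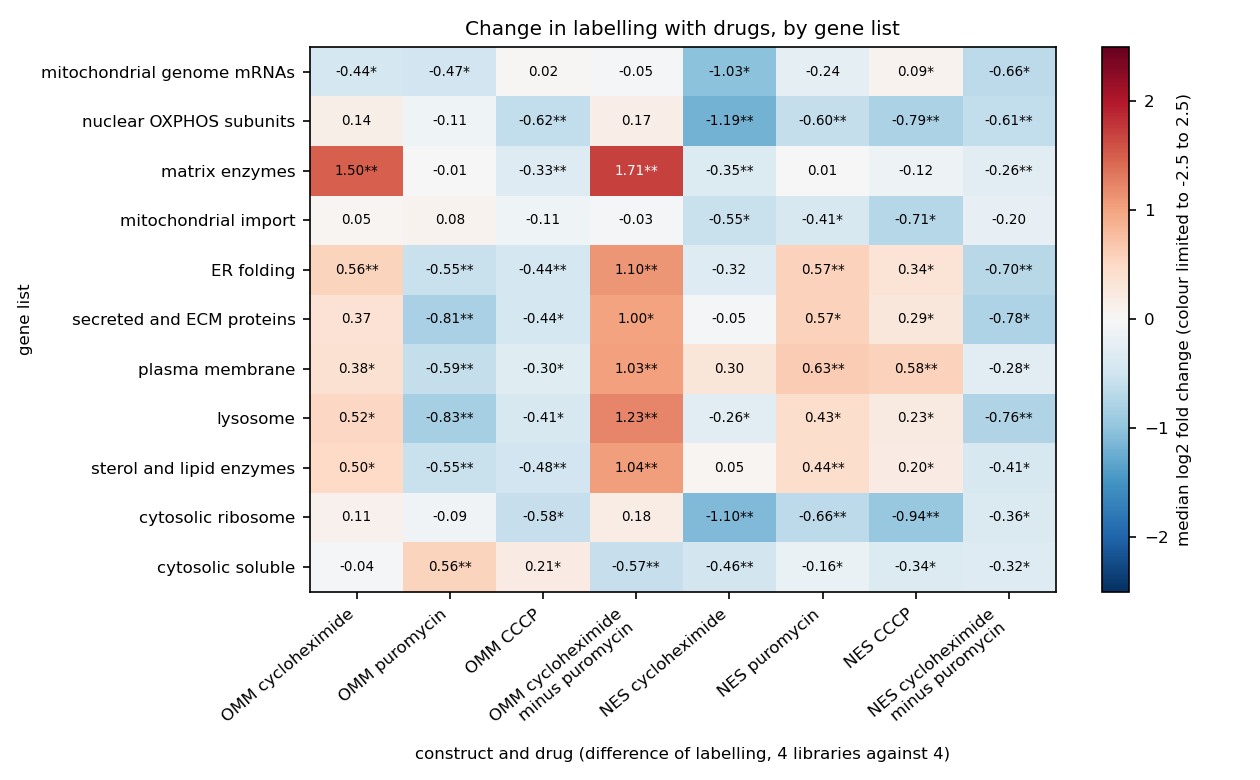
Median log2 fold change of each gene list (colour) for each drug against untreated cells and for cycloheximide against puromycin, in OMM and NES labelling. A star marks a list with an adjusted p under 0.05 at the preset correlation and 2 stars one that also passed with an estimated correlation.

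Puromycin, which releases nascent chains from ribosomes, lowered OMM labelling of the matrix proteins PDPR (-3.39 ± 0.32), GLDC (-3.21 ± 0.53), LARS2 (-3.03 ± 0.31), IARS2 (-2.93 ± 0.25) and ALDH18A1 (-2.89 ± 0.24), and of the ER products P4HB (-1.27 ± 0.21), SCD (-1.26 ± 0.19) and CALU (-1.23 ± 0.20). The chaperonin subunit CCT8 (1.61 ± 0.20) and the proteasome subunit PSMD3 (1.57 ± 0.25) rose. Matrix enzymes had 0 of 88 higher and 11 lower (2 and 14 within the list, median -0.01, adjusted p = 0.0983). ER folding had 0 of 63 higher and 3 lower (0 and 11 within the list, median -0.55, adjusted p = 2.62e-10), lysosome 0 of 62 higher and 2 lower (0 and 10 within the list, median -0.83, adjusted p = 3.11e-14) and soluble cytosolic proteins 3 of 60 higher and 0 lower (18 and 0 within the list, median 0.56, adjusted p = 1.29e-18). Higher genes numbered 17 and lower genes 53 of 22078 (11 and 77 with RLE size factors, a shift of -0.11 in the median of all genes). OMM puromycin calls rose without untreated unlabelled 1 and fell without any other library. GLDC was not called with only the libraries of the comparison (adjusted p = 0.064). For matrix enzymes the adjusted p was 2.11e-05 by DESeq2, 0.0116 with RLE size factors, 0.00136 with no filter on low counts, 0.0267 between the labelled libraries alone (median 0.16), 0.0127 without low-complexity libraries and 0.0316 among genes with a mean of at least 5 CPM. Matrix enzymes had a list adjusted p = 0.0214 without untreated labelled 2 and 0.0104 without untreated unlabelled 2.

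Set directly against each other at the OMM, cycloheximide gave more LARS2 (4.71 ± 0.32), ALDH18A1 (4.42 ± 0.25) and IARS2 (4.35 ± 0.25) than puromycin, and more CALU (1.68 ± 0.20), CANX (1.55 ± 0.19), SCD (1.48 ± 0.19) and HSPA5 (1.17 ± 0.19). FASN (-1.85 ± 0.39), the cytosolic fatty acid synthase, the chaperonin subunits CCT8 (-1.24 ± 0.20) and CCT5 (-1.03 ± 0.20) and TUBB (-0.81 ± 0.16) were lower. Matrix enzymes had 45 of 88 higher and 0 lower (50 and 0 within the list, median 1.71, adjusted p = 8.28e-30). ER folding had 23 of 63 higher and 0 lower (31 and 0 within the list, median 1.10, adjusted p = 1.09e-17) and soluble cytosolic proteins 0 of 60 higher and 11 lower (0 and 20 within the list, median -0.57, adjusted p = 3.8e-15). With cycloheximide against puromycin 782 genes were higher and 193 lower of 22078, and RLE size factors shifted the median of all genes by 0.11. Of OMM cycloheximide against puromycin calls 189 had a group without a count and 71 a group of 1 to 3 counts. OMM cycloheximide against puromycin calls rose without cycloheximide unlabelled 1 or 2 and fell without any other library. OMM cycloheximide against puromycin counts were 1597 with only the libraries of the comparison.

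CCCP, which collapses the membrane potential needed for protein import, lowered OMM labelling of GLDC (-3.98 ± 0.54), IARS2 (-3.09 ± 0.25), ALDH18A1 (-3.05 ± 0.24) and LARS2 (-2.49 ± 0.31). Matrix enzymes had 0 of 88 higher and 10 lower (1 and 16 within the list, median -0.33, adjusted p = 5.7e-11) and ribosomal transcripts 0 of 76 higher and 2 lower (0 and 21 within the list, median -0.58, adjusted p = 1.76e-20, adjusted p = 0.101 with an estimated correlation). ER folding had 0 of 63 called (0 and 3 within the list, median -0.44, adjusted p = 2.66e-08), sterol and lipid enzymes 0 of 59 called (0 and 0 within the list, median -0.48, adjusted p = 1.75e-07) and the respiratory chain 0 of 76 higher and 1 lower (0 and 6 within the list, median -0.62, adjusted p = 2.24e-14), while the single gene SCD (-0.65 ± 0.19) was not called. CCCP left 6 genes higher and 25 lower of 22078. OMM CCCP calls numbered 15 without CCCP labelled 1, 12 without CCCP labelled 2, 74 without CCCP unlabelled 1, 14 without untreated labelled 1, 16 without untreated labelled 2 and 597 without untreated unlabelled 1. OMM CCCP counts were 12 with only the libraries of the comparison. GLDC and LARS2 were not called with only the libraries of the comparison (adjusted p = 0.141 and 0.0792). SCD was called by DESeq2 (adjusted p = 0.00815) and SCD with no filter on low counts (adjusted p = 0.0422).

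With cycloheximide, NES labelling of ribosomal and respiratory messages such as RPS15 (-2.53 ± 0.36), RPL18 (-1.61 ± 0.25), RPL37A (-1.52 ± 0.22) and COX8A (-2.27 ± 0.37) fell. Ribosomal transcripts had 0 of 76 higher and 38 lower (0 and 56 within the list, median -1.10, adjusted p = 1.44e-49) and the respiratory chain 1 of 76 higher and 17 lower (1 and 52 within the list, median -1.19, adjusted p = 3.51e-33). In total 37 genes were higher and 174 lower of 22078. Untreated NES unlabelled 1 lacked 3.18 percent of well-expressed genes. NES cycloheximide calls rose without cycloheximide unlabelled 2 or untreated unlabelled 2 and fell without any other library. NES cycloheximide counts were 0 with only the libraries of the comparison (edgeR, 2090 at an unadjusted p under 0.05).

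Puromycin raised NES labelling of the ER chaperone CANX (1.25 ± 0.19). ER folding had 4 of 63 higher and 0 lower (24 and 3 within the list, median 0.57, adjusted p = 6.82e-10) and ribosomal transcripts 0 of 76 called (0 and 43 within the list, median -0.66, adjusted p = 3.01e-35). Genes higher were 14 and genes lower 3 of 22078, and NES puromycin unlabelled 2 lacked 2.24 percent of well-expressed genes. NES puromycin calls numbered 3 without puromycin labelled 1, 4 without puromycin labelled 2, 154 without puromycin unlabelled 1, 6 without untreated unlabelled 1, 801 without untreated unlabelled 2 and 0 without each of untreated labelled 1 and untreated labelled 2 (edgeR, 924 and 961 at an unadjusted p under 0.05). NES puromycin counts were 0 with only the libraries of the comparison (edgeR, 1535 at an unadjusted p under 0.05). Cycloheximide against puromycin lowered the ER chaperones PDIA3 (-1.59 ± 0.24) and CALR (-1.19 ± 0.19) in NES labelling, and ER folding had 0 of 63 higher and 5 lower (0 and 23 within the list, median -0.70, adjusted p = 1.26e-17). Higher genes came to 2 and lower genes to 17. NES cycloheximide against puromycin calls numbered 9 without cycloheximide unlabelled 1, 287 without cycloheximide unlabelled 2, 6 without puromycin labelled 2, 142 without puromycin unlabelled 1, 11 without puromycin unlabelled 2 and 0 without each of cycloheximide labelled 2 and puromycin labelled 1 (edgeR, 1192 and 1243 at an unadjusted p under 0.05). NES cycloheximide against puromycin counts were 0 with only the libraries of the comparison (edgeR, 1952 at an unadjusted p under 0.05).

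With CCCP, NES labelling of the ribosomal FAU (-1.80 ± 0.33) was lower. Ribosomal transcripts had 0 of 76 higher and 6 lower (0 and 52 within the list, median -0.94, adjusted p = 2.79e-46). Their fall with each drug was not told from a difference between sets. Calls were 6 higher and 12 lower of 22078, and 1 and 2 with RLE size factors. NES CCCP calls rose without untreated unlabelled 2 and fell without any other library. NES CCCP counts were 3 with RLE size factors and 0 with only the libraries of the comparison (edgeR, 1874 at an unadjusted p under 0.05). FAU lost its call without each of CCCP labelled 1, CCCP labelled 2, CCCP unlabelled 1, CCCP unlabelled 2 and untreated unlabelled 1. FAU was not called with RLE size factors (adjusted p = 0.053) and FAU between the labelled libraries alone (adjusted p = 0.0555).

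The nocodazole series asked how microtubule loss changes OMM and NES labelling, each labelled time set against unlabelled libraries of 3 and 30 min. At 3 min OMM labelling held ALDH18A1 (3.07 ± 0.17) and the secretory CANX (2.08 ± 0.13), CALU (2.22 ± 0.15), PSAP (1.78 ± 0.13) and SCD (1.95 ± 0.12), while RPL5 (-1.32 ± 0.14) and MT-RNR2 (-1.41 ± 0.16) were lower. ALDH18A1 stood at 3.03 ± 0.17, 2.03 ± 0.17, 1.65 ± 0.17 and 1.42 ± 0.17 at 6, 9, 30 min and 2 h. TUBB, a beta tubulin whose message decays when free tubulin builds up, was lower at 9 min (-0.96 ± 0.12), 30 min (-0.81 ± 0.12) and 2 h (-1.40 ± 0.12). Secreted protein transcripts had 37 of 76 higher and 1 lower (46 and 1 within the list, median 1.53, adjusted p = 2.58e-10) at 3 min and 26 of 76 higher and 0 lower (28 and 0 within the list, median 0.92, adjusted p = 4.5e-06) at 2 h, ER folding 30 of 63 higher and 3 lower (32 and 6 within the list, median 0.75, adjusted p = 0.000366) and 17 of 63 higher and 6 lower (21 and 6 within the list, median 0.26, adjusted p = 0.256), and mitochondrial messenger RNAs 0 of 13 higher and 13 lower (0 and 13 within the list, median -1.10, adjusted p = 2.3e-23) and 0 of 13 higher and 13 lower (0 and 13 within the list, median -1.92, adjusted p = 3.41e-29). Genes higher and lower at the OMM, of 19611 tested, were 2167 and 368 at 3 min, 2398 and 589 at 6 min, 2166 and 496 at 9 min, 1991 and 409 at 30 min, and 1917 and 566 at 2 h. A group had no count in 1228, 1308, 1208, 1137 and 1012 of the calls at these times. The OMM unlabelled libraries lacked 11.55 and 13.48 percent (3 min) and 2.96 and 16.28 percent (30 min) of well-expressed genes. With the NES unlabelled libraries as controls, chosen after the data were seen, the counts were 295 and 145, 416 and 360, 255 and 259, 186 and 172, and 287 and 309. OMM 3 min calls numbered 1176 without 3 min labelled 1, 1031 without 3 min labelled 2 and 4652 without 30 min unlabelled 1. OMM 3 min counts were 1632 with only the libraries of the comparison. For ER folding at 3 min the adjusted p was 0.0877 with only the libraries of the comparison. OMM 6 min calls numbered 1369 without 6 min labelled 1, 1283 without 6 min labelled 2 and 5050 without 30 min unlabelled 1. OMM 9 min calls numbered 1355 without 9 min labelled 1, 1345 without 9 min labelled 2 and 4709 without 30 min unlabelled 1. OMM 9 min counts were 21 with only the libraries of the comparison. At 9 min ALDH18A1 and TUBB were not called with only the libraries of the comparison (adjusted p = 0.0739 and 0.154). OMM 30 min calls numbered 1233 without 30 min labelled 1, 1044 without 30 min labelled 2, 3714 without 3 min unlabelled 1 and 4647 without 30 min unlabelled 1. OMM 30 min counts were 15 with only the libraries of the comparison and 767 with the controls of the nearest time. At 30 min ALDH18A1 and TUBB were not called with only the libraries of the comparison (adjusted p = 0.134 and 0.147). OMM 2 h calls numbered 1507 without 2 h labelled 1, 3930 without 3 min unlabelled 1 and 4589 without 30 min unlabelled 1. OMM 2 h counts were 23 with only the libraries of the comparison and 914 with the controls of the nearest time. At 2 h ALDH18A1 and TUBB were not called with only the libraries of the comparison (adjusted p = 0.155 and 0.0929). For ER folding at 2 h the adjusted p was 0.000153 with the NES unlabelled libraries as controls.

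Between labelled libraries alone, 2 h of nocodazole against 3 min raised the immediate early gene JUN (3.22 ± 0.25) and the BH3-only PMAIP1 (2.06 ± 0.27) in OMM labelling, and lowered TUBB (-1.08 ± 0.14), ALDH18A1 (-1.65 ± 0.20), PSAP (-1.22 ± 0.16), the ER isomerase P4HB (-1.38 ± 0.20) and MT-ND1 (-1.37 ± 0.18), which also fell without labelling. Immediate early genes had 4 of 54 higher and 0 lower (5 and 1 within the list, median 0.68, adjusted p = 5.69e-07). Tubulins had 0 of 12 higher and 2 lower (0 and 4 within the list, median -0.88, adjusted p = 0.000558, adjusted p = 0.0824 with an estimated correlation) and ER folding 0 of 63 higher and 9 lower (0 and 18 within the list, median -0.52, adjusted p = 0.000135). No unlabelled library at 2 h tells a change of RNA amount from one of labelling, in OMM or NES. JUN and TUBB moved the same way in NES labelling. By 2 h 28 genes were higher and 60 lower of 19611. OMM 2 h labelled 1 lacked 4.59 percent of well-expressed genes. OMM 2 h against 3 min calls fell without any 1 library. OMM 2 h against 3 min counts were 0 with only the libraries of the comparison (edgeR, 3413 at an unadjusted p under 0.05).

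**Figure D5:**
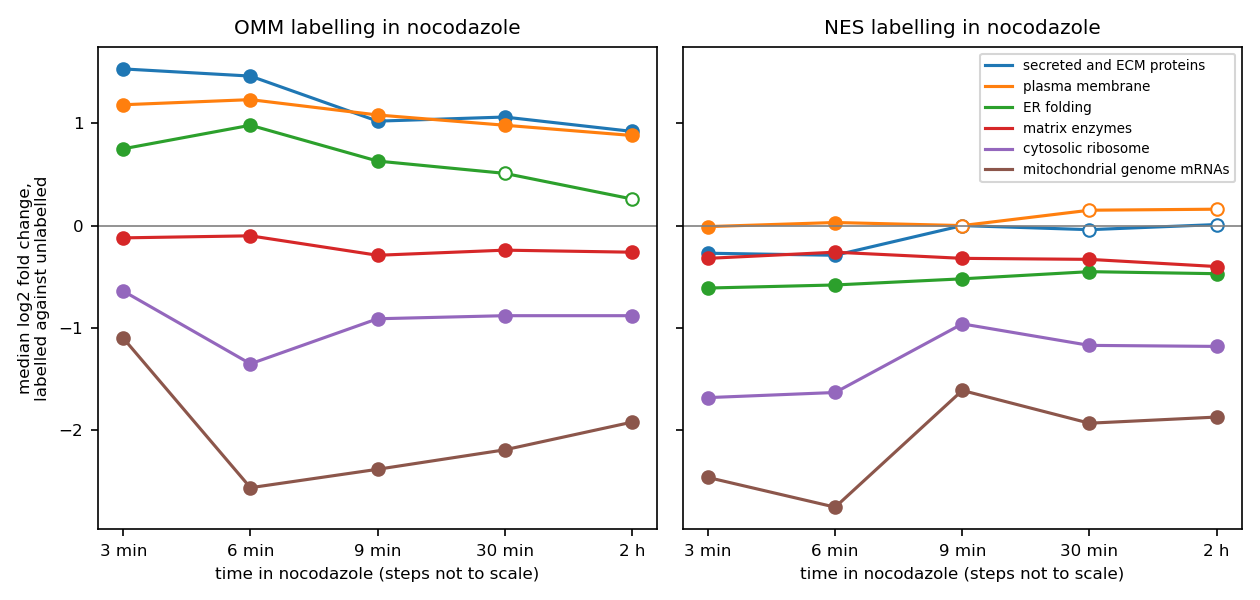
Median log2 fold change (labelled against unlabelled, y axis) of gene lists at each time of nocodazole (x axis), OMM and NES in separate panels. Filled symbols have a list adjusted p under 0.05.

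NES labelling at 3 min of nocodazole was low in RPS6 (-2.33 ± 0.18), RPL5 (-1.82 ± 0.15) and MT-RNR2 (-2.47 ± 0.17) and in the ER chaperones HSPA5 (-1.03 ± 0.17) and HSP90B1 (-1.15 ± 0.12). TUBB was not called at 3 min (0.00 ± 0.12) or 9 min (-0.39 ± 0.12) and was lower by 2 h (-1.12 ± 0.12), when JUN was higher (2.51 ± 0.19). HSPA5 was not called at 2 h (-0.48 ± 0.16), and RPL5 remained lower (-1.28 ± 0.14). Ribosomal transcripts had 0 of 76 higher and 65 lower (0 and 71 within the list, median -1.68, adjusted p = 5.06e-101) at 3 min and 0 of 76 higher and 59 lower (0 and 67 within the list, median -1.18, adjusted p = 1.5e-65) at 2 h. Genes higher and lower in NES labelling, of 19611, were 188 and 419 at 3 min, 284 and 466 at 6 min, 72 and 162 at 9 min, 156 and 274 at 30 min, and 264 and 354 at 2 h. NES 3 min unlabelled 2 lacked 6.78 percent of well-expressed genes. NES 3 min calls numbered 244 without 3 min labelled 1, 164 without 3 min labelled 2, 914 without 3 min unlabelled 1 and 1500 without 30 min unlabelled 1. NES 3 min counts were 106 with only the libraries of the comparison. At 3 min HSPA5 and HSP90B1 were not called with only the libraries of the comparison (adjusted p = 0.0541 and 0.0566). NES 6 min calls numbered 216 without 6 min labelled 1, 256 without 6 min labelled 2 and 1592 without 30 min unlabelled 1. NES 6 min counts were 99 with only the libraries of the comparison and 487 with the controls of the nearest time. NES 9 min calls rose without 3 min unlabelled 1 or 30 min unlabelled 1 and fell without any other library. NES 9 min counts were 5 with only the libraries of the comparison and 105 with the controls of the nearest time. At 9 min TUBB was called with no filter on low counts (adjusted p = 0.00777) and TUBB without low-complexity libraries (adjusted p = 0.029). NES 30 min calls numbered 54 without 30 min labelled 1, 41 without 30 min labelled 2, 670 without 3 min unlabelled 1, 233 without 3 min unlabelled 2, 1291 without 30 min unlabelled 1 and 264 without 30 min unlabelled 2. NES 30 min counts were 19 with only the libraries of the comparison. NES 2 h calls numbered 99 without 2 h labelled 1, 185 without 2 h labelled 2, 356 without 3 min unlabelled 2 and 1479 without 30 min unlabelled 1. NES 2 h counts were 208 with only the libraries of the comparison. At 2 h HSPA5 was called with no filter on low counts (adjusted p = 0.0179) and HSPA5 without low-complexity libraries (adjusted p = 0.0193).

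Between NES labelled libraries alone, JUN (2.04 ± 0.23) and EIF5 (1.32 ± 0.16) were higher and TUBB (-1.11 ± 0.14) lower at 2 h than at 3 min; EIF5 also rose without labelling (1.18 ± 0.15 at 30 against 3 min). Tubulins had 0 of 12 higher and 2 lower (0 and 4 within the list, median -1.01, adjusted p = 1.39e-07) and ribosomal transcripts 0 of 76 called (18 and 0 within the list, median 0.47, adjusted p = 3.41e-29). This left 3 genes higher and 2 lower of 19611, and 5 and 2 with RLE size factors. NES 2 h against 3 min calls numbered 3 without 3 min labelled 2. NES 2 h against 3 min counts were 10 with only the libraries of the comparison.

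The change from 3 min to 2 h differed between OMM and NES for ALDH18A1 (-1.7 ± 0.28), which fell in OMM labelling relative to NES labelling. ER folding had 0 of 63 higher and 1 lower (0 and 18 within the list, median -0.76, adjusted p = 1.41e-14) and secreted proteins 0 of 76 called (0 and 6 within the list, median -0.87, adjusted p = 1.44e-08). Of 19611 genes compared 0 were higher and 4 lower. With 1 library left out ALDH18A1 kept its call only without OMM 2 h labelled 2 (adjusted p = 0.0412). OMM against NES over time calls numbered 22 without OMM 2 h labelled 2 and 0 without each of OMM 3 min labelled 1, OMM 3 min labelled 2, OMM 2 h labelled 1, NES 3 min labelled 2, NES 2 h labelled 1 and NES 2 h labelled 2 (edgeR, 577, 797, 700, 378, 754 and 868 at an unadjusted p under 0.05). OMM against NES over time counts were 1 with only the libraries of the comparison. ALDH18A1 lost its call without NES 3 min labelled 1 (adjusted p = 0.0856).

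Unlabelled OMM libraries of 30 and 3 min of nocodazole differed, but lacked 2.96 and 16.28 percent (30 min) and 11.55 and 13.48 percent (3 min) of well-expressed genes. FOSB, an immediate early gene without counts at 30 min, was lower at least 1720-fold against a floor of 3 counts, MT-RNR2 (-1.66 ± 0.17) and MT-ND1 (-0.95 ± 0.18) were lower, and immediate early genes had 0 of 54 higher and 5 lower (1 and 6 within the list, median -0.44 (-0.54 with bounds), adjusted p = 4.62e-05). At 30 min 938 genes were higher and 351 lower of 19611. Of OMM unlabelled calls 460 had a group without a count and 285 a group of 1 to 3 counts. OMM unlabelled calls numbered 3011 without 3 min unlabelled 1, 2114 without 3 min unlabelled 2 and 3359 without 30 min unlabelled 1. OMM unlabelled counts were 0 with only the libraries of the comparison (edgeR, 293 at an unadjusted p under 0.05). In the NES construct the ribosomal RNAs MT-RNR1 (-1.57 ± 0.22) and MT-RNR2 (-1.04 ± 0.17) were lower and EIF5 (1.18 ± 0.15) was higher, and no other gene was called. NES unlabelled calls numbered 171 without 3 min unlabelled 1, 884 without 30 min unlabelled 1 and 0 without each of 3 min unlabelled 2 and 30 min unlabelled 2 (edgeR, 809 and 659 at an unadjusted p under 0.05). NES unlabelled counts were 0 with only the libraries of the comparison (edgeR, 326 at an unadjusted p under 0.05). MT-RNR2 was not called among genes with a mean of at least 5 CPM (adjusted p = 0.0749).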

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

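The tests weighed here were fixed before their results were seen, except that the tests of a hold by ribosomes were chosen after the matrix enzyme result was seen.

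Differences between groups were met by the labelling contrasts of the 9 constructs: 870 genes differed between ERM and NES labelling, 391 between OMM and NES labelling and 516 between NLS and NES labelling. With drugs, 410 genes differed in OMM labelling with cycloheximide, 70 with puromycin and 31 with CCCP, and 975 between cycloheximide and puromycin. In NES labelling the numbers were 211 with cycloheximide, 17 with puromycin, 18 with CCCP and 19 between cycloheximide and puromycin. The change from 3 min to 2 h of nocodazole differed between OMM and NES labelling in 4 genes, among them ALDH18A1, but in 0 genes (edgeR, 378 to 868 at an unadjusted p under 0.05) in 6 of 8 tests with 1 library left out, and ALDH18A1 kept its call in 1 of the 8. Data that enter no comparison of their own held 1 signal: in the technical repeat of MITO labelled 2 the mitochondrial genome took 61.3 percent of counts, against 58.82 percent in labelled 2, 45.58 percent in labelled 1 and 8.47 and 5.03 percent in the unlabelled libraries. Across well-expressed genes its log2 CPM correlated with labelled 2 at 0.924, below the 0.96 of labelled 1 and above unlabelled libraries (0.883 and 0.896). The repeat had 14346 genes with a count, against 19151 in labelled 2 and 18784 in labelled 1. Genes without a count can lower the correlation, so it does not decide how close the repeat is.

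Matrix enzyme transcripts such as HADHA, HADHB and CS were higher in OMM labelling with cycloheximide, with a list median of 1.5. Few distinct transcripts in the cycloheximide unlabelled libraries are argued against as the source, because the median was 1.61 between labelled libraries alone. Transcript length bias is argued against too, because the highest 2.5 percent of matched random lists began at 0.19. A hold by ribosomes and their nascent chains over the whole list stays open: puromycin gave a list median of -0.01, with 11 of 88 lower and 0 higher (adjusted p = 0.0983). In the 9 matrix enzyme genes higher at the OMM at 3 min of nocodazole against NES unlabelled libraries, controls chosen after the data were seen, which hold none of those named above, puromycin gave a median of -2.16, with 8 called lower, as a hold would need. CCCP gave a median of -2.34 in those genes, so the test does not tell loss of ribosomes from loss of import.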

How the results depend on the processing

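Tests without low-complexity libraries, among genes with a mean of at least 5 CPM for counts, and with NES unlabelled libraries as controls were chosen after the data were seen. Under other settings 1657 gene results kept direction and side of the threshold, 67 lost the call, 19 gained one and 3 turned direction. Genes were chosen partly by results with 1 library left out, so those cannot test them. Under other settings 704 list results kept direction and side of the threshold, 16 lost the call, 12 gained one and 1 turned direction. With 1 library left out 491 list results kept direction and side of the threshold, 3 lost the call, 6 gained one. Direction turned for MT-CO1 in NLS (0.12 to -0.89 with the controls of all 9 constructs), MT-ND6 in LMA (1.05 to -0.37 with the controls of all 9 constructs) and FAS in OMM cycloheximide (a lower bound of 9.09 to -0.38 with the labelled libraries alone). The list test alone turned, while the median kept its sign, for mitochondrial messenger RNAs in KDEL (0.51 to 0.12 with the controls of all 9 constructs, adjusted p = 0.673); the cause was not tested in any of these. By DESeq2 the counts were NLS 2227, NIK 2682, LMA 3026, NucPore 177, NES 1663, OMM 1832, MITO 522, ERM against NES 1612, OMM against NES 762, NLS against NES 1070, MITO total RNA 436, MITO poly(A) against total RNA 6, OMM cycloheximide 1575, OMM puromycin 377, OMM CCCP 531, OMM cycloheximide against puromycin 2405, NES cycloheximide 1011, NES puromycin 464, NES CCCP 311, NES cycloheximide against puromycin 580, OMM 3 min 4146, OMM 9 min 4245, OMM 30 min 4123, OMM 2 h 4382, OMM 2 h against 3 min 988, OMM unlabelled 3791, NES 3 min 1455, NES 6 min 1509, NES 9 min 809, NES 30 min 1159, NES 2 h 1548, NES 2 h against 3 min 98, NES unlabelled 382 and OMM against NES over time 296. With only the libraries of the comparison in the model they were NLS 4788, NIK 0, LMA 4417, NES 0, ERM 1857, OMM 463, ERM against NES 353, OMM against NES 130, MITO total RNA 50, OMM cycloheximide 41, OMM CCCP 12, OMM cycloheximide against puromycin 1597, NES cycloheximide 0, NES puromycin 0, NES CCCP 0, NES cycloheximide against puromycin 0, OMM 3 min 1632, OMM 9 min 21, OMM 30 min 15, OMM 2 h 23, OMM 2 h against 3 min 0, OMM unlabelled 0, NES 3 min 106, NES 6 min 99, NES 9 min 5, NES 30 min 19, NES 2 h 208, NES 2 h against 3 min 10, NES unlabelled 0 and OMM against NES over time 1. The controls of all 9 constructs gave NLS 5994, NIK 4471, LMA 6881, NucPore 1429, NES 1637, ERM 5025, KDEL 1, OMM 3006 and MITO 993. Asking a log2 fold change of at least 1 as well left NLS 775 and NES 566. No filter on low counts gave NucPore 13, KDEL 10, MITO total RNA 288, MITO poly(A) against total RNA 8, OMM puromycin 162, OMM CCCP 101, NES cycloheximide 392, NES puromycin 119, NES CCCP 110, NES cycloheximide against puromycin 60, OMM 2 h against 3 min 180, NES 9 min 399, NES 2 h against 3 min 20, NES unlabelled 21 and OMM against NES over time 42. A replicate block gave NucPore 10, KDEL 2, MITO total RNA 13, OMM puromycin 129, OMM CCCP 75, NES cycloheximide 351, NES puromycin 60, NES CCCP 92 and NES cycloheximide against puromycin 40. Dropping low-complexity libraries gave NucPore 39, ERM 4457, ERM against NES 1448, OMM against NES 661, NLS against NES 1732, MITO total RNA 26, OMM puromycin 414, OMM CCCP 710, NES cycloheximide 736, NES puromycin 235, NES CCCP 150, NES cycloheximide against puromycin 983, OMM 2 h against 3 min 450, NES 3 min 1531, NES 6 min 1631, NES 9 min 731, NES 30 min 1108, NES 2 h 1658, NES unlabelled 10 and OMM against NES over time 65. Among genes with a mean of at least 5 CPM values were NucPore 1, Fractionation 7125, OMM puromycin 121, OMM CCCP 51, NES cycloheximide 330, NES puromycin 32, OMM 2 h against 3 min 155, NES 9 min 386 and correlation of labelling between constructs 0.12 (0.03 in the main setting). Labelled libraries alone gave OMM cycloheximide 246, OMM puromycin 771, OMM CCCP 369, NES cycloheximide 429, NES puromycin 60 and NES CCCP 56. RLE size factors gave NES CCCP 3. NES unlabelled libraries as controls gave OMM 3 min 440, OMM 6 min 776, OMM 9 min 514, OMM 30 min 358 and OMM 2 h 596. Controls of the nearest time gave OMM 30 min 767, OMM 2 h 914, NES 6 min 487 and NES 9 min 105. Leaving out 1 library in turn gave NLS 435 to 642, NIK 541 to 2441, LMA 802 to 1227, NucPore 0 to 174, NES 117 to 2075, ERM 1905 to 3110, OMM 441 to 2180, MITO 108 to 253, ERM against NES 494 to 2009, OMM against NES 168 to 1113, NLS against NES 223 to 1301, MITO total RNA 0 to 641, MITO poly(A) against total RNA 0 to 1, OMM cycloheximide 186 to 2727, OMM puromycin 24 to 700, OMM CCCP 12 to 597, OMM cycloheximide against puromycin 450 to 3142, NES cycloheximide 16 to 1591, NES puromycin 0 to 801, NES CCCP 0 to 1036, NES cycloheximide against puromycin 0 to 287, OMM 3 min 1031 to 4652, OMM 6 min 1283 to 5050, OMM 9 min 1345 to 4709, OMM 30 min 1044 to 4647, OMM 2 h 1507 to 4589, OMM 2 h against 3 min 18 to 75, OMM unlabelled 1301 to 3359, NES 3 min 164 to 1500, NES 6 min 216 to 1592, NES 9 min 11 to 1128, NES 30 min 41 to 1291, NES 2 h 99 to 1479, NES 2 h against 3 min 3 to 5, NES unlabelled 0 to 884, OMM against NES over time 0 to 22. The cause of these changes was not tested. Lists called over all comparisons numbered 481 of 872 and 304 with an estimated correlation, 480 by DESeq2 and 485 with RLE size factors. Replicates share a number in the labels and nothing else was given to tie them: over 21 pairs of groups the correlation of replicate differences had a median of -0.01, ran from -0.17 to 0.15, and was above 0.1 in 1 and below -0.1 in 1, so groups were not paired. Removal of low-complexity libraries was not run for NIK, OMM with cycloheximide and the OMM nocodazole times, where a whole group would have gone.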

Other observations

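Mitochondrial ribosome transcripts, made mostly on free ribosomes, were low at the ER surface. In ERM labelling MRPL51 (-2.59 ± 0.29), MRPL21 (-3.21 ± 0.39) and MRPL14 (-2.58 ± 0.33) of the large mitoribosomal subunit fell, and of the list 0 of 76 were higher and 46 lower (0 and 56 within the list, median -1.19, adjusted p = 1.03e-21). Transcripts of heat and oxidative stress proteins were low in the nucleus: in NLS labelling the peroxiredoxin PRDX1 (-1.11 ± 0.16) and the ferritin FTL (-1.10 ± 0.20) fell, and the list had 0 of 36 higher and 9 lower (0 and 12 within the list, median -0.50, mean 0.28 and test downward, adjusted p = 2.05e-08). In LMA labelling PRDX1 (-1.17 ± 0.16), FTL (-1.44 ± 0.21) and FTH1 (-1.17 ± 0.24) fell, and the list had 0 of 36 higher and 10 lower (0 and 14 within the list, median -0.71, adjusted p = 5.97e-08).

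In the nuclear fraction HIST1H2BK (-1.37 ± 0.20) and HIST1H4C (-3.59 ± 0.71, cytosol 1.4 and 10 CPM) were lower, HIST4H4 and HIST3H2BB higher. Histones had 5 of 27 higher and 9 lower (4 and 8 within the list, median -0.45, adjusted p = 0.177). Markers of other cell types were scarce. ACTA1 (2.44 ± 0.37) and COL3A1 (2.45 ± 0.42) were higher there (mean 1.03 and 0.629 CPM). The list had 4 of 8 higher and 1 lower (4 and 1 within the list, median 0.95, adjusted p = 0.298). By the main test neither list was called in any comparison (lowest adjusted p = 0.107 for histones in LMA and 0.11 for markers of other cell types in OMM with cycloheximide), but with no filter on low counts histones were called lower in the nuclear fraction (median -0.27, adjusted p = 0.0254).

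Tests of transcript length bias within constructs, of chance in the poly(A) libraries and of sequence by gene type were chosen after the results were seen. Cytosolic ribosomal protein transcripts were lower with NLS, NIK, LMA, NES, ERM and OMM. Transcript length bias as the whole source in LMA, NES, ERM and OMM is argued against. In 4 of these 4 constructs, and so 4 of all 6, the list median lay below the lowest 2.5 percent of 10000 random lists. These were matched on mean CPM and on the length of the longest transcript, and again on that of the principal one. A part stays open. Random medians on the principal transcript were -0.88, -0.63, -1.42 and -0.52, nearer the list medians (-1.08, -1.02, -2 and -0.81) than those on the longest. Transcript length bias in NLS and NIK stays open, because 0 of these 2 medians lay below both ranges. Matched on the longest transcript, the test fixed before, both lay below (-0.79 against -0.74 to -0.53, and -0.62 against -0.58 to -0.31). Matched on the principal transcript, both lay within (-0.81 to -0.61, and -0.65 to -0.37). The longest transcripts of these genes had a median of 1841.5 bases against 1079.5 for the principal ones, so the first match compares them with longer messages. GC content bias is argued against in 6 of 6 constructs.

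Nuclear-encoded transcripts such as TUBA1B and KIF11 were higher in poly(A) libraries after MITO labelling, 183 in all with a median of 1.65. Chance in the poly(A) libraries alone is argued against, because their median was 1.29 in the total RNA libraries, where 182 were positive and 56 called higher. Both kinds of library share sample numbers and may share samples, so chance in the labelling itself stays open. Sequence shared with mitochondrial transcripts on the same strand remains possible for the set, with a mean longest exact match of 16.2 bases (random lists 12.8 to 13.1), through the 9 genes that are not protein-coding, with 80.4 bases (11.7 to 13), of which 3 match over at least 141 bases. In the 174 protein-coding genes it is argued against, with 12.9 bases (12.8 to 13.1). Base pairing with mitochondrial transcripts is argued against in the set and in its protein-coding genes, with 13.1 bases in each (12.9 to 13.2), and remains possible for the 9 others, with 13.3 bases (11.7 to 13). What places TUBA1B in MITO labelling was not found.

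The authors' deposited p values under 0.05 gave, as higher and lower genes, 1269 and 1270 in NLS, 1372 and 3226 in NIK, 1365 and 1591 in LMA, 166 and 573 in NucPore, 419 and 1342 in NES, 1886 and 3604 in ERM, 0 and 0 in KDEL, 1235 and 1352 in OMM and 491 and 178 in MITO. Replicate log2 fold changes correlated across genes, which are not independent replicates, at 0.5 in NLS (0.63 among well-expressed genes), 0.43 in LMA (0.59), 0.35 in ERM (0.55), 0.21 in NES (0.31), 0.18 in OMM (0.33), 0.17 in MITO (0.31), 0.16 in NIK (0.22), 0.09 in KDEL (0.11) and 0.03 in NucPore (0.08).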
